A study of Mus musculus with 36 samples.

How the data were processed

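Livers of male C57BL/6N mice were sampled in 6 groups of 6: month 0 control, olive oil for 2 or 12 months, and CCl4 for 2, 6 or 12 months. Per the labels' protocols, CCl4 was injected at 1 g per kg of body weight in olive oil, total RNA was extracted with TRIzol, ribosomal RNA was removed, and stranded paired-end libraries were sequenced. The titles of the month 0 mice say control, while their treatment label says olive oil. Raw counts, 1 whole number per gene symbol and library, were deposited as a table of 32544 symbols by 36 libraries. Per the submitters' processing notes the reads were mapped with Biojupies to mm10, and edgeR 3.30.3 and limma 3.44.3 were used. The gene annotation behind the counts is not given in the sources used here. The read files and any other analysis by the submitters were not used here.

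Groups, comparisons, gene lists, the rule for naming genes and most alternatives were fixed from the labels before the data were examined. The 8 comparisons were CCl4 against oil at months 2 and 12, CCl4 at month 6 against the mean of month 2 and month 12 oil on the log scale, the interaction of CCl4 and month (12 against 2), month 12 against month 2 oil, month 2 oil against month 0, and CCl4 month 6 against 2 and 12 against 6. Genes were filtered with filterByExpr (15338 kept), scaled by TMM (factors between 0.757 and 1.33) and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, in 1 fit of the 36 libraries without an intercept. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes, within each comparison. Fold changes are log2 values with a standard error taken from the fitted effect and its F statistic. Levels are given as CPM, counts scaled to a common total after TMM.

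Lists of at least 5 tested genes, 38 in all, were tested with camera in limma 3.58.1 on log-CPM with a prior count of 1, once with the preset inter-gene correlation of 0.01 and once with a correlation estimated for each list, adjusted over the lists of a comparison. A count "adjusted over the list alone" applies the Benjamini-Hochberg correction to the members of that list only. List levels per mouse are means of log2(CPM + 1). List levels of cell markers and other tissues were compared between CCl4 and oil at months 2 and 12 (36 tests) by a two-sided exact permutation test of the difference in means, whose smallest p for 6 against 6 is 0.00216, adjusted over the 36 tests. With a pseudocount of 0.1 or 5 in place of 1 these tests called 14 and 12 in place of 13.

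Genes were named by rule: those with the highest and lowest fold change among called genes with a mean of at least 1 CPM and, for CCl4 against oil, complete separation of the treated mice from each oil mouse (8 per direction, and 5 per direction elsewhere, without that separation); a panel of 21 genes; and, per described list, the 3 members with the smallest p and the members called against the list median. Predicted genes, mitochondrial, immunoglobulin and T cell receptor symbols were left out of the ranking. The lists described one by one, and the genes named outside this rule (among them Fgf21), were chosen after the values were seen. Positions were taken from GENCODE vM21 on mm10 by symbol, for 533 of 534 named genes.

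Alternatives comprised RLE size factors, library totals alone, no low-count filter, a filter of 1 CPM in 6 samples, the replicate number as a block, DESeq2 1.42.0, limma-voom, a fit of the compared groups only, other reference groups and leaving out each library in turn. Another 5 were chosen after seeing the data. They included the list tests and the list levels without each library in turn. Covariates were the pancreas list level and, for time of day, the ratio of Arntl to Dbp. The last left out 4 libraries with transcripts of other tissues or blood cells. These were month 2 CCl4 replicates 1 and 6, month 2 oil replicate 2 and month 12 oil replicate 2. Month 6 CCl4 replicate 2, with the highest mesothelial level, and libraries high in pancreas transcripts were kept. Random regroupings of the compared mice were refitted, 70 for the interaction and 100 for each other comparison, the real grouping among them.

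The procedure was tested on simulated data, 15199 genes with the means, dispersions and totals of the fitted data and known changes at month 2. It called 87% of 2-fold and 99% of 4-fold genes, with median fitted log2 changes of 0.958 and 1.98 and 0 calls of the wrong sign. Of the calls 8% were unchanged genes, above the nominal 5%. No pair of libraries in a group was a copy of the other: the lowest chi-square per degree of freedom among 90 replicate pairs was 24.65. Of the 36 libraries, none was left out of the main comparisons. Floors (3 counts over a group) and intervals of count ratios (95%, exact) take the whole numbers as reads without molecular identifiers. They cover counting error only. The sources used here do not state whether the numbers are rounded estimates. Near-identical genes share reads, which the counts do not resolve.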

Results

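Gene-level read counts were analysed from whole livers of 36 male C57BL/6N mice, 6 in each of 6 groups. Mice received carbon tetrachloride (CCl4), a hepatotoxin that hepatocytes convert to radicals, in olive oil for 2, 6 or 12 months, or olive oil alone for 2 or 12 months. The remaining group carried the title of month 0 control. CCl4-treated livers were taken on day 6 after the last injection. Each library held between 19,403,247 and 28,917,545 counts over 32544 gene symbols, and 15338 genes had enough counts to be tested. Totals ran from 21,141,657 to 27,323,562 at month 0, from 23,760,704 to 28,917,545 in month 2 oil, from 22,078,882 to 28,166,011 in month 2 CCl4, from 19,403,247 to 27,323,706 in month 6 CCl4, from 24,904,742 to 28,364,932 in month 12 oil and from 21,812,315 to 26,237,784 in month 12 CCl4. All fold changes below are log2 values from 1 edgeR fit of the 36 libraries, with their standard error (SE), and gene positions are those of mm10. Levels are counts scaled to a common library total (CPM), as mean ± SD over 6 mice.

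**Figure D1:**
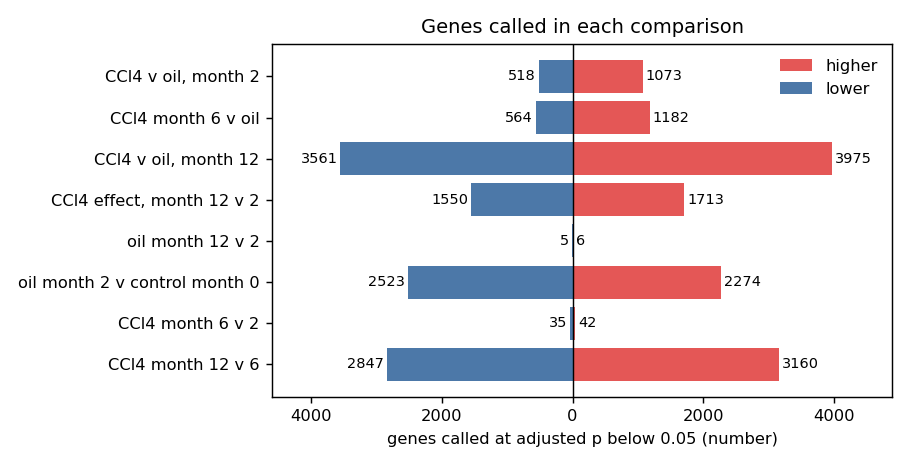
Number of genes called at an adjusted p below 0.05 in each of 8 comparisons (bars, higher and lower drawn separately, of 15338 genes tested). CCl4 against oil called 1591 genes at month 2 and 7536 at month 12.

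The comparison of CCl4 with oil at month 2 asked what early chronic injury changed. Livers exposed to CCl4 for 2 months carried more transcripts of fibrillar collagens, of other matrix proteins and of macrophage markers, and fewer of the male-biased genes of hepatocytes, although none of these lists was called with an estimated correlation (adjusted p = 0.193 for each). Col1a1, which encodes a chain of type I collagen (chromosome 11, 94,936,224 to 94,953,042), rose from 13.6 ± 8.4 to 36 ± 7.01 CPM (log2 fold change 1.40, SE 0.36, adjusted p = 0.0105). Col3a1 rose by 1.28 (SE 0.31). Trem2, a lipid receptor of macrophages in injured liver (chromosome 17, 48,346,401 to 48,354,147), rose from 7.04 ± 1.78 to 13.1 ± 1.76 CPM (adjusted p = 0.00321). Susd4, a complement regulator with higher expression in male liver (chromosome 1, 182,763,860 to 182,896,591), decreased by 4.37 on the log2 scale (SE 0.34, adjusted p = 1.17e-10), from 27.9 ± 4.45 to 1.34 ± 0.228 CPM.

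In all, 1591 genes were called at month 2, of which 1073 were higher and 518 lower. With the 4 libraries with transcripts of other tissues or blood cells left out, 884 were called (540 higher and 344 lower). At least 2-fold changes were seen in 326 higher and 134 lower genes, and 3764 genes had an unadjusted p below 0.05. Scaling by library totals alone moved the median of all genes by 0.199 and called 3160 genes higher and 179 lower, so changes here are relative to the median gene. The highest fold changes among genes with complete separation of the 12 mice were those of Lyz1 (3.35), Hamp2 (3.16), Tcf24 (2.87), Scube1 (2.84, SE 0.31, adjusted p = 1.84e-07), Gldn (2.72), Fgd1 (2.43), S100a8 (2.42) and Sirpb1a (2.39). Scube1 encodes a secreted cell-surface protein (chromosome 15, 83,604,999 to 83,725,021) and rose from 0.309 ± 0.124 to 2.27 ± 1.11 CPM. The lowest were those of Mup19 (-9.07), Mup-ps16 (-7.76), Mup15 (-7.05), Mup17 (-6.12), Cyp2c69 (-5.78), Fitm1 (-5.58), Susd4 and Cyp2c40 (-4.22). Reads of the near-identical Mup genes and of Cyp2c40 and Cyp2c69 cannot be assigned with certainty to 1 member. Gstm3, a glutathione transferase, rose by 1.22 (SE 0.25). Acta2 (-0.04), Timp1 (0.31), Lox (0.71), Krt19 (1.48), Spp1 (0.91), Clec4f (-0.20), Cd3e (-0.77), Stab2 (0.17), Cyp2e1 (-0.73), Cyp7a1 (-0.39), Glul (-0.82), Cyp2f2 (0.38), Alb (-0.35), Mki67 (0.85), Cdkn1a (1.08), Afp (0.52) and Saa1 (1.55) were not called at month 2.

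Of 36 matrix structure genes, 23 rose and none fell (26 and 0 adjusted over the list alone), among them Col6a3 (1.45), Lama2 (1.66) and Lum (1.71). The list median was 0.74 (camera adjusted p = 7.7e-21, and adjusted p = 0.193 with an estimated correlation). Macrophage markers of monocyte origin rose in 13 of 20 genes (17 adjusted over the list alone), including Cd63 (1.25), Cx3cr1 (1.31) and Itgax (1.22), with a median of 1.04 (adjusted p = 2.14e-10, and adjusted p = 0.193 with an estimated correlation). Among 27 male-biased hepatocyte genes, 12 fell and none rose (15 and 0 adjusted over the list alone), with a median of -0.96 (adjusted p = 2.43e-13, and adjusted p = 0.193 with an estimated correlation). Susd4, Mup21 (-3.73) and Cyp2u1 (-1.60) had the smallest p-values of that list. Cholesterol synthesis genes had a median of -0.48 (adjusted p = 1.24e-08, and adjusted p = 0.307 with an estimated correlation). Of these 25 genes, 6 fell (16 adjusted over the list alone), including Hsd17b7 (-1.17), Msmo1 (-0.93) and Cyp51 (-0.68, not called when scaled by totals alone). Pericentral hepatocyte genes fell in 8 and rose in 2 of 30 (12 and 2 adjusted over the list alone). Cyp2c37 (-2.55), Lhpp (-2.20) and Oat (-2.34) fell, whereas Car2 (1.44) and Rhbg (1.20) rose. That list had a median of -0.34 (adjusted p = 8.34e-06, and adjusted p = 0.34 with an estimated correlation).

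Neutrophil markers rose in 8 of 10 genes (9 adjusted over the list alone), with a median of 2.23 (adjusted p = 3.03e-05, and adjusted p = 0.307 with an estimated correlation). They were highest in month 2 CCl4 replicate 1, and without this library the fold changes of S100a8 and S100a9 dropped from 2.42 in each to 0.92 and 1.02 and were not called. Retnlg (2.00) kept its call without it and lost it when the 4 libraries with transcripts of other tissues or blood cells were left out. Erythroid and blood transcripts, also highest in replicate 1, rose in 2 of 15 genes (9 adjusted over the list alone), with a median of 1.03 (adjusted p = 0.0466, and adjusted p = 0.566 with an estimated correlation). That list was not called with library totals alone (adjusted p = 0.47), nor without month 2 CCl4 replicate 1 (adjusted p = 0.342) or 4 or month 2 oil replicate 2, 3 or 6 (adjusted p between 0.0601 and 0.121). Cholangiocyte and ductular markers rose in 4 of 19 genes (8 adjusted over the list alone), with a median of 0.91 (adjusted p = 0.0366, and adjusted p = 0.527 with an estimated correlation). The list was not called without month 2 CCl4 replicate 6 (adjusted p = 0.357), which also held intestinal transcripts, nor without month 2 CCl4 replicate 5 (adjusted p = 0.0731) or month 2 oil replicate 4 or 5 (adjusted p = 0.0536 and adjusted p = 0.0712). Without month 2 CCl4 replicate 6 the fold changes were 0.08 for Epcam (2.51 with it), -1.12 for Cftr (3.48) and 0.58 for Cldn4 (2.58), and outside the list 1.67 for Lyz1 (3.35), none of them called. Cldn4 also lost its call without month 2 oil replicate 1, 4 or 5 (2.32, 2.51 and 2.35). The cholangiocyte list was not called under scaling by library totals alone (adjusted p = 0.654). At month 2, 25 of the 38 lists were called with the preset correlation and 0 with the estimated one. In levels per mouse, macrophage markers were 0.817 higher and neutrophil markers 0.774 higher on the log2 scale, each with the smallest p that exact permutations of 6 against 6 mice can give (0.00216, adjusted 0.00779 over 36 tests). Without month 2 CCl4 replicate 1 the difference in neutrophil markers was 0.408. Kupffer cell markers rose in 4 of 16 genes at month 2 (8 adjusted over the list alone), with a median of 0.43 (adjusted p = 0.0031, and adjusted p = 0.527 with an estimated correlation).

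**Figure D2:**
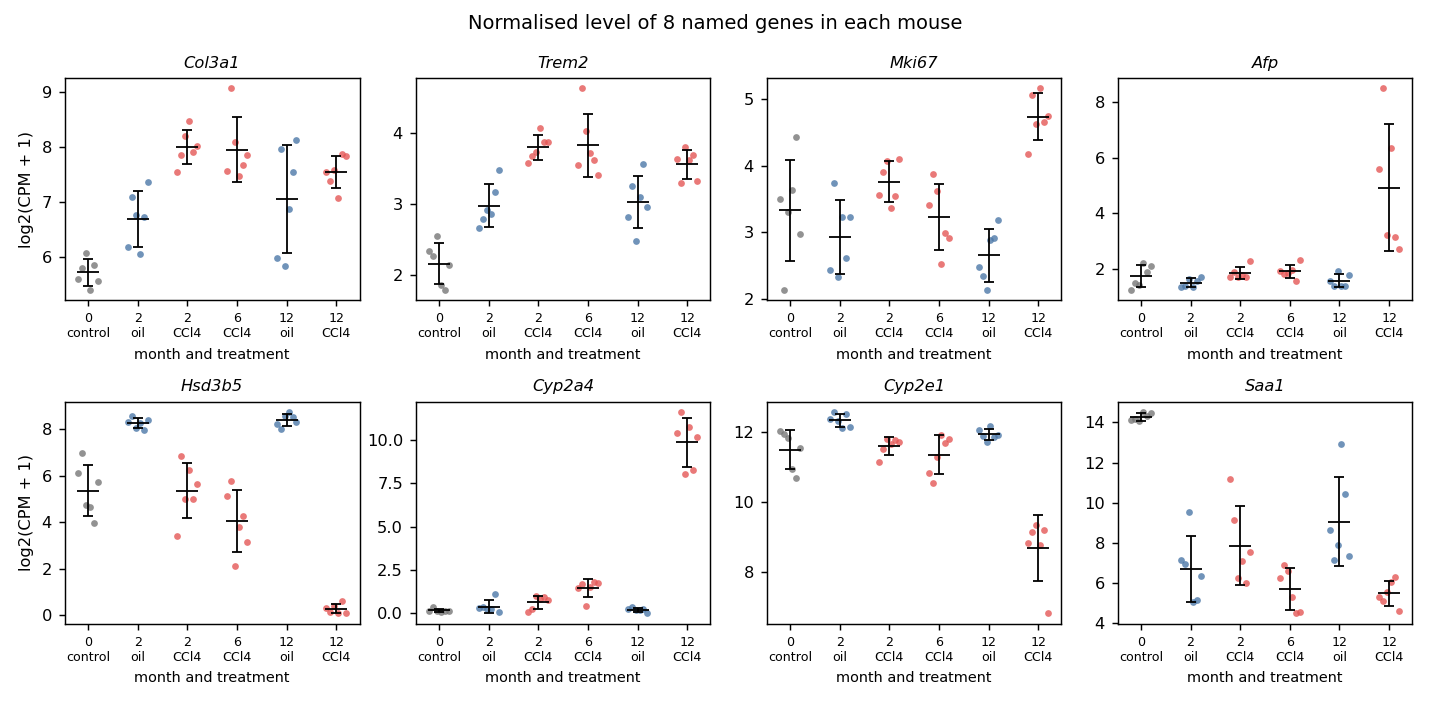
Level of 8 genes in each of 36 livers, as log2 of CPM plus 1, by group (points are mice, lines and bars are mean ± SD, n = 6). Hsd3b5 averaged 309 CPM in month 2 oil and 0.215 CPM in month 12 CCl4.

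After 6 months of CCl4 no oil group of the same age was at hand, so the treated mice were compared with the mean of the month 2 and month 12 oil groups on the log scale. The question was which changes of chronic injury were present midway through the course. As at month 2, matrix and macrophage transcripts were higher and male-biased transcripts lower, and single markers of resident macrophages fell, without a call for their list, and no list was called with an estimated correlation. Cd163, a haemoglobin scavenger receptor of resident macrophages (chromosome 6, 124,304,656 to 124,330,527), decreased by 2.92 (SE 0.22, adjusted p = 2.69e-11), to 5.00 ± 1.9 CPM. Fbn2, which encodes a microfibril protein (chromosome 18, 58,008,623 to 58,210,487), rose by 3.26 (SE 0.26, adjusted p = 1.11e-10). Col1a1 reached 41.1 ± 18.3 CPM (log2 fold change 1.20, SE 0.30, adjusted p = 0.00672).

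At month 6, 1746 genes were called (1182 higher and 564 lower), 290 of them at least 2-fold higher and 144 at least 2-fold lower, and 3756 passed an unadjusted p of 0.05. Library totals alone moved the median gene by 0.313 and called 8884 genes higher and 177 lower. Without month 6 CCl4 replicate 2 the count was 1049. Against month 12 oil alone 1115 genes were called. Besides Fbn2, the highest fold changes among genes with complete separation of treated and oil mice were those of Ly6d (2.88), Scube1 (2.70, SE 0.25), Cdh19 (2.64), Tcf24 (2.52), Sytl5 (2.48) and Fhl2 (2.46). Sult2a2 had no count in the oil libraries and 18 counts in month 6 CCl4, at least 10.1-fold higher against a floor of 3 counts over the group. The lowest among genes with such separation were those of Mup19 (-8.26), Mup17 (-6.46), Mup15 (-6.25), Mup12 (-5.50), Mup9 (-5.24), Mup-ps16 (-5.09), Cfd (-4.76) and Susd4 (-4.41, SE 0.32). Trem2 rose by 0.94 (SE 0.17, adjusted p = 0.00019). Gstm3 rose by 0.73 and lost its call without month 6 CCl4 replicate 1 or 3 (0.64 and 0.68). Saa1 decreased by 3.19 on the log2 scale, and by 1.62 with no call against month 2 oil alone. Acta2 (-0.37), Timp1 (0.69), Lox (0.70), Krt19 (0.57), Clec4f (-0.44), Cd3e (-0.06), Stab2 (0.08), Cyp7a1 (-0.36), Cyp2f2 (0.10), Alb (-0.36), Mki67 (0.50), Cdkn1a (0.73) and Afp (0.55) were not called at month 6.

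Matrix structure genes rose in 22 of 36 at month 6 and fell in none (30 and 0 adjusted over the list alone), with Col6a3 (1.18), Lama2 (1.27) and Lum (1.29) as examples (median 0.69, adjusted p = 4e-18, and adjusted p = 0.126 with an estimated correlation). Macrophage markers of monocyte origin rose in 16 of 20 (17 adjusted over the list alone), including Cd63 (1.41), Gpnmb (2.37) and Itgax (1.59), with adjusted p = 4.37e-14, and adjusted p = 0.123 with an estimated correlation. Male-biased genes fell in 16 of 27 (21 adjusted over the list alone), including Slco1a1 (-2.72) and Moxd1 (-9.34), with adjusted p = 2.99e-23, and adjusted p = 0.0614 with an estimated correlation. Kupffer cell markers were not called as a list (adjusted p = 0.0623), although Cd163, Timd4 (-1.88) and Xlr (-0.86) fell. With library totals alone that list was called lower (adjusted p = 0.000228), as it was without month 2 oil replicate 3 or 5, month 6 CCl4 replicate 1, 2 or 4, or month 12 oil replicate 6 (adjusted p between 0.00724 and 0.048). Pericentral genes fell in 11 and rose in 2 of 30 (14 and 2 adjusted over the list alone), with adjusted p = 1.77e-07, and adjusted p = 0.27 with an estimated correlation. Cyp2c37 (-2.55), Lhpp (-1.71) and Cyp2c50 (-1.16) fell, and Car2 rose by 0.94. Rhbg (0.77) lost its call without month 6 CCl4 replicate 3, 4, 5 or 6 or month 12 oil replicate 1 (between 0.70 and 0.76). Acute phase genes fell in 6 and rose in 1 of 24 (13 and 1 adjusted over the list alone), with adjusted p = 5.24e-07, and adjusted p = 0.306 with an estimated correlation. Saa4 (-1.23) and Itih4 (-0.58) fell. Saa3 (1.24) was called higher and lost its call without month 2 oil replicate 1, 3 or 4, month 6 CCl4 replicate 1, 2, 3 or 5, or month 12 oil replicate 1, 3 or 6 (between 0.68 and 1.30).

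Lipogenesis genes rose in 8 of 28 at month 6 (11 adjusted over the list alone), including Scd2 (1.5), Cd36 (1.18) and Acaca (0.60), with adjusted p = 5.26e-05, and adjusted p = 0.27 with an estimated correlation. Cholesterol synthesis genes rose in 3 of 25 (4 adjusted over the list alone), with adjusted p = 0.0011, and adjusted p = 0.544 with an estimated correlation. Neither list was called with library totals alone (adjusted p = 0.0995 and adjusted p = 0.0937). Several calls rested on month 6 CCl4 replicate 2. Without it the fold changes were 0.93 for Col1a1, 0.72 for Col3a1 (1.04 with it), 0.71 for Spp1 (1.17), 0.39 for Lss (0.76) and 0.54 for Mvd (0.84), none of them called. Mvd was not called without month 6 CCl4 replicate 1 or 3 either (0.81 and 0.80). Cyp2e1 (-0.71) lost its call without month 2 oil replicate 1, 2, 3 or 5, month 6 CCl4 replicate 1, 2 or 3, or month 12 oil replicate 1, 4 or 6 (between -0.72 and -0.58). Glul (-0.83) lost it without any 1 of the month 6 CCl4 libraries, without month 2 oil replicate 1, 2, 3, 4 or 5, and without month 12 oil replicate 3 or 4 (between -0.86 and -0.79). Of the 38 lists, 25 were called with the preset correlation and 0 with the estimated one.

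The comparison at month 12 asked what a year of CCl4 changed relative to oil of the same age. Transcripts of male-biased hepatocyte genes dropped steeply, those of female-biased genes, of the cell cycle, of the list of oxidative stress and glutathione genes and of the list of oncofetal and tumour-associated genes rose, and those of the urea cycle and amino acid catabolism fell. With an estimated correlation the cell cycle, glutathione and amino acid lists were not called, and 6 of 31 genes of the glutathione list fell. Cyp2a4, a steroid hydroxylase with higher expression in female liver (chromosome 7, 26,307,169 to 26,315,088), rose from 0.159 ± 0.102 to 1313 ± 1050 CPM (log2 fold change 13, SE 0.78, adjusted p = 9.6e-15). Hsd3b5, a male-specific steroid reductase (chromosome 3, 98,618,634 to 98,630,252), dropped from 340 ± 60.5 to 0.215 ± 0.175 CPM (log2 fold change -10.6, SE 0.79, adjusted p = 1.73e-12). Slco1a1, an organic anion carrier (chromosome 6, 141,907,282 to 141,946,962), decreased by 7.41 (SE 0.38). Nqo1, a quinone reductase (chromosome 8, 107,388,225 to 107,403,206), rose from 4.26 ± 0.954 to 69.9 ± 20.6 CPM (log2 fold change 4.03, SE 0.23, adjusted p = 1.24e-15). Afp, the fetal counterpart of albumin (chromosome 5, 90,490,737 to 90,508,907), rose from 2.01 ± 0.49 to 85.2 ± 138 CPM (log2 fold change 5.41, SE 0.69).

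A total of 7536 genes were called at month 12, 3975 higher and 3561 lower, with 1619 at least 2-fold higher and 567 at least 2-fold lower, and 8419 had an unadjusted p below 0.05. Library totals alone shifted the median gene by 0.556 and called 10331 genes higher and 592 lower. Akr1c18 (8.78, SE 0.82), Tekt5 (8.47), Vil1 (8.17) and Csn3 (8.00) were among the highest fold changes. Vil1 ran from 11.6 to 187 CPM in month 12 CCl4, highest in replicate 6, and was at most 0.361 CPM in month 12 oil. Sult2a2 had no count in month 12 oil and was at least 492-fold higher in CCl4. With the deposited whole numbers taken as reads, Apela had 1 count in the oil group, a ratio of 2740 with a counting interval from 492 to 108000, and Sult2a1 had 2 counts, a ratio of 673 with an interval from 186 to 5560. These intervals pool the mice of a group and leave out variation between mice. As log2 of CPM plus 1, Sult2a1 was at 5.54 in month 12 CCl4 replicate 1 and at most 2.47 in the other mice of that group. Reads of Sult2a1 and Sult2a2, and of Cyp2a4 and Cyp2a5, may be shared between near-identical copies. The lowest among genes with complete separation of treated and oil mice were Moxd1 (-12.2, SE 1.3), Mup7 (-12.1), Mup15 (-12.0), Mup12 (-11.9), Hsd3b5, Mup11 (-10.2), Mup17 (-10.2) and Mup9 (-9.66). Gstm3 (4.07, SE 0.28), Spp1 (3.24), Cdkn1a (2.91) and Mki67 (2.26) rose. Cyp2e1, the cytochrome that activates CCl4 (chromosome 7, 140,763,739 to 140,774,987), decreased by 3.08 (SE 0.29), from 3953 ± 424 to 468 ± 193 CPM. Cyp2f2 (-1.05) and Saa1 (-5.16, and -2.02 with no call against month 2 oil) also fell, as did Glul (-0.94, not called with library totals alone). Trem2 rose by 0.56 and lost its call without month 12 oil replicate 1 or 3 (0.49 and 0.44). Col1a1 (0.66), Col3a1 (0.26), Acta2 (0.43), Timp1 (-0.44), Lox (0.04), Krt19 (-0.37), Clec4f (-0.30), Cd3e (0.60), Stab2 (-0.15), Cyp7a1 (-1.46) and Alb (0.24) were not called. Of these, Col1a1 was called without month 12 oil replicate 2 or 6 (0.883 and 0.984), Cd3e without month 12 oil replicate 2 (0.98), Clec4f without month 12 CCl4 replicate 4 (-0.476), and Cyp7a1 without month 12 oil replicate 1 or 5 or month 12 CCl4 replicate 5 (-1.69, -1.66 and -1.8). In month 12 oil Col1a1 stood at 23.5 ± 17.9 CPM and Col3a1 at 157 ± 94.1 CPM, with the highest levels in month 12 oil replicates 6 (47.7 and 278 CPM) and 2 (42.7 and 246 CPM).

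Male-biased genes fell in 26 of 27 and rose in none at month 12 (26 and 0 adjusted over the list alone), including C8b (-2.47), with a median of -3.34 (adjusted p = 1.5e-20, and adjusted p = 0.0353 with an estimated correlation). Female-biased genes rose in 24 of 29 and fell in 1, Prlr (-0.65), with a median of 2.37 (adjusted p = 3.2e-10, and adjusted p = 0.0353 with an estimated correlation). Rtn4 rose by 1.99. Cell cycle genes rose in 34 of 35, including Mcm6 (2.19), Cenpf (3.05) and Cdk1 (2.67), with a median of 2.14 (adjusted p = 1.19e-16, and adjusted p = 0.0818 with an estimated correlation). Oncofetal genes rose in 18 of 23, including Scd2 (3.95), Ly6d (7.43) and Golm1 (2.91), and Egfr (-1.62) fell (adjusted p = 2.4e-09, and adjusted p = 0.0211 with an estimated correlation). Glutathione and oxidative stress genes rose in 20 of 31 and fell in 6, with a median of 0.98 (adjusted p = 8.9e-06, and adjusted p = 0.0724 with an estimated correlation). Gstm1 rose by 2.35. Cat (-0.62), Gpx1 (-0.67), Gstp1 (-0.89), Gstt1 (-0.42), Sod1 (-0.50) and Sod2 (-0.46) fell, but with library totals alone the first 3 were not called and the others turned to 0.12, 0.04 and 0.09. Gstt1 also lost its call without month 12 CCl4 replicate 6 (-0.32). Genes of the urea cycle and amino acid catabolism fell in 30 of 33, including Cbs (-1.14), Dmgdh (-1.44) and Kmo (-0.91), with adjusted p = 3.2e-10, and adjusted p = 0.292 with an estimated correlation. Pericentral genes fell in 19 and rose in 4 of 30 (21 and 4 adjusted over the list alone). Cyp2c50 (-2.33) was among those that fell, and Blvrb (1.15), Car2 (2.00), Cyp2a5 (1.87) and Slc1a4 (2.50) rose (adjusted p = 3.22e-06, and adjusted p = 0.292 with an estimated correlation).

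Matrix structure genes rose in 20 and fell in 2 of 36 at month 12, with a median of 0.69 (adjusted p = 3.22e-05, and adjusted p = 0.433 with an estimated correlation). The basement membrane chains Col4a1 (1.79) and Col4a2 (1.54) and Col6a3 (1.34) rose. Dcn (-0.53) fell, with no call under library totals alone. Efemp1 (-0.63) was called lower and lost its call without month 12 oil replicate 2 (-0.32) or month 12 CCl4 replicate 2, 3 or 4 (-0.48, -0.58 and -0.61). Macrophage markers of monocyte origin rose in 15 of 20, including Cd63 (3.16), Lpl (2.13) and Cx3cr1 (2.30), with adjusted p = 2.44e-06, and adjusted p = 0.272 with an estimated correlation. Cholangiocyte markers rose in 13 of 19, including Anxa13 (5.57), Prom1 (3.70) and Pkhd1 (1.31), with adjusted p = 5.01e-06, and adjusted p = 0.14 with an estimated correlation. Krt19 of this list was not called, and Prom1 is also a member of the female-biased and oncofetal lists. Markers of quiescent stellate cells fell in 11 and rose in 5 of 19 (12 and 5 adjusted over the list alone), with adjusted p = 0.0163, and adjusted p = 0.418 with an estimated correlation. Hhip, a hedgehog antagonist (chromosome 8, 79,965,851 to 80,058,006), dropped from 7.31 ± 1.14 to 0.0407 CPM (log2 fold change -7.37, SE 0.33), and Angptl6 fell (-1.67). Cygb (1.01), Rgs5 (0.85) and Tcf21 (0.66) were among those that rose. In levels per mouse, cholangiocyte (1.43), macrophage (1.28), vascular endothelial (0.909) and dendritic cell (0.748) markers were higher and quiescent stellate markers lower (-0.387). Each of these had the smallest p that exact permutations can give (0.00216, adjusted 0.00779). No difference was called for pancreas transcripts (adjusted exact permutation p = 0.586). Of the 38 lists, 25 were called with the preset correlation and 3 with the estimated one.

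**Figure D3:**
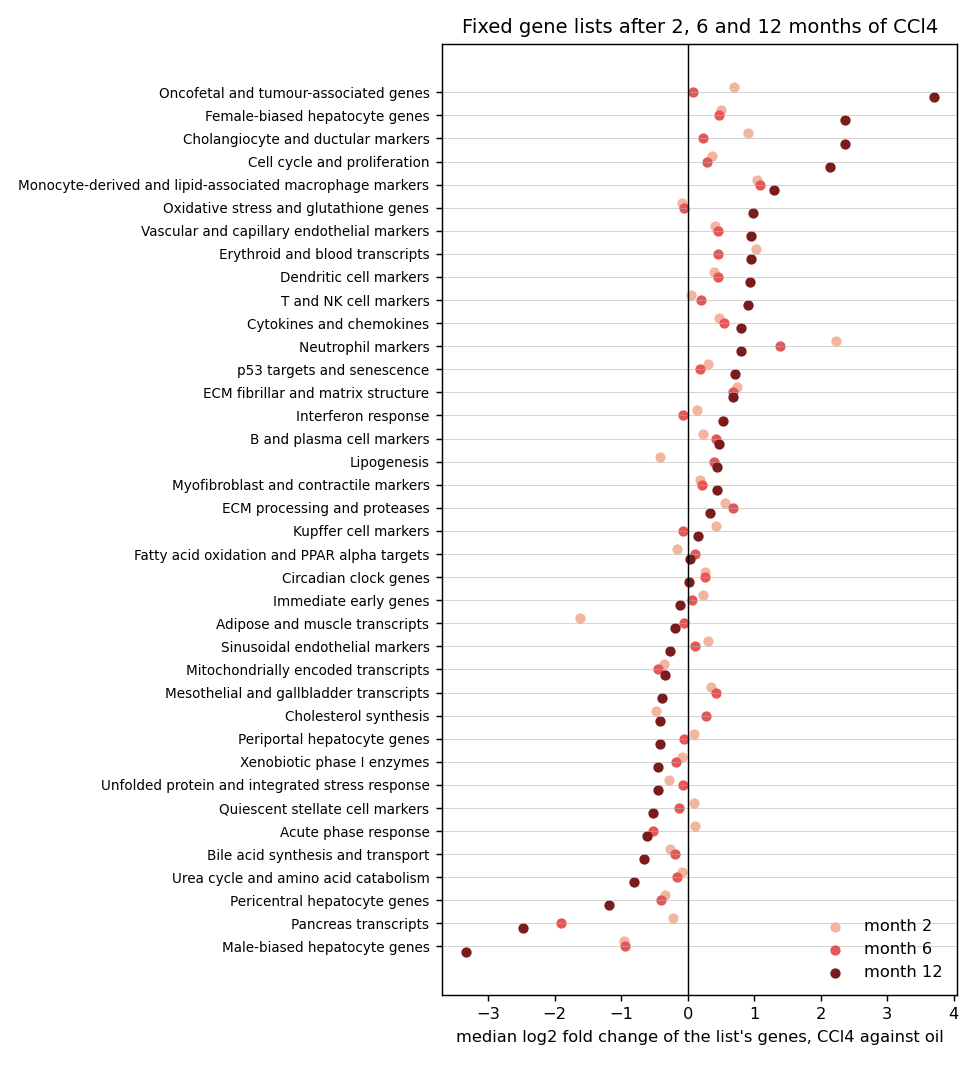
Median log2 fold change of 38 gene lists for CCl4 against oil at months 2, 6 and 12 (horizontal axis in log2 units, 1 colour per month). The male-biased list has medians of -0.96, -0.94 and -3.34.

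Whether the effect of CCl4 differed between months 12 and 2 was tested as an interaction, which takes each month's oil group as its own reference. The lists of female-biased, glutathione and cell cycle genes had a higher effect at month 12, and the list of male-biased genes a lower one, of which the cell cycle and male-biased lists were not called with an estimated correlation (adjusted p = 0.0782 and adjusted p = 0.0651). The effect on Hsd3b5 differed by -7.96 (SE 0.88, adjusted p = 5.72e-08) and that on Nqo1 by 3.78 (SE 0.30, adjusted p = 7.04e-11). Fgf21, a hormone of hepatocytes under metabolic stress, was lower at month 2 (-1.84) and higher at month 12 (3.88), a difference of 5.72 (SE 0.67, adjusted p = 1.71e-07). Pparg, a regulator of lipid storage, was also lower at month 2 (-1.43) and higher at month 12 (1.13).

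The interaction was called for 3263 genes, 1713 with a higher and 1550 with a lower effect at month 12, and 5065 had an unadjusted p below 0.05. Differences of at least 2-fold were seen in 857 and 374 of them. Library totals alone shifted the median by 0.346 and called 5115 and 438. The highest were Cyp2a4 (12.1), Cyp2b9 (10.3, and 7.05 without month 2 oil replicate 5), Apela (10.1), Csn3 (8.54) and Akr1c18 (7.76). Apela lost its call without month 2 oil replicate 1 (8.89). The lowest were Mup7 (-10.0), Hsd3b5, Mup12 (-7.87), Saa2 (-7.68) and Mup1 (-7.22). Reads of Cyp2b9 and Saa2 may be shared with near-identical copies. Cell cycle genes had a higher effect at month 12 in 32 of 35 (33 adjusted over the list alone), including Rrm2 (1.82), Cenpf (2.71) and Mcm6 (1.83), with adjusted p = 1.55e-17, and adjusted p = 0.0782 with an estimated correlation. Female-biased genes had a higher effect in 18 of 29 (22 adjusted over the list alone), including Prom1 (3.00), with adjusted p = 2.92e-13, and adjusted p = 0.0126 with an estimated correlation. Male-biased genes had a lower effect in 18 of 27 (22 adjusted over the list alone), including Slco1a1 (-5.91) and C8b (-2.24), with adjusted p = 1.22e-16, and adjusted p = 0.0651 with an estimated correlation. Oncofetal genes had a higher effect in 12 of 23, including Igf2 (6.55) and Ly6d (5.94), and a lower one for Egfr (-1.40), with adjusted p = 5.01e-10, and adjusted p = 0.0126 with an estimated correlation. Glutathione genes had a higher effect in 17 and a lower one in 2 of 31 (18 and 3 adjusted over the list alone), with adjusted p = 3.4e-09, and adjusted p = 0.0128 with an estimated correlation. Gstm4 (2.09) and Gstm1 (2.38) were higher, Gpx1 (-0.90) was lower, and Sod3 (-0.57) lost its call without month 2 oil replicate 4 or 5, month 2 CCl4 replicate 1 or 3, month 12 oil replicate 2 or month 12 CCl4 replicate 2, 5 or 6 (between -0.52 and -0.47). Lipogenesis genes had a higher effect in 10 of 28 (11 higher and 2 lower adjusted over the list alone), including Pparg (2.56), Plin4 (3.69) and Scd2 (2.43), with adjusted p = 3.07e-04, and adjusted p = 0.334 with an estimated correlation. Part of this lay in the oil groups: from month 2 to 12 the mean list level fell from 6.367 to 5.932 in oil and rose from 6.137 to 6.446 in CCl4. The matrix structure list was not called (adjusted p = 0.375). Among all 38 lists, 21 were called with the preset correlation and 3 with the estimated one.

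The months were also set side by side by the genes they shared. Of the genes called at month 2, 70.4% were called in the same direction at month 12 (exact 95% interval 68.1 to 72.6). That share was 805 higher and 315 lower genes, against 278 and 120 by chance from the product of the list sizes. The interval treats genes as independent, which they are not, and leaves out variation between mice. Opposite directions were called in 12 genes that were higher and then lower and in 44 that were lower and then higher, and 50 genes differed in sign with a called difference and a mean of at least 1 CPM. Plin4 (-1.40 and 2.29) was among these. For independent oil groups, month 2 CCl4 against month 2 oil and month 6 CCl4 against month 12 oil shared 361 higher and 151 lower genes (46 and 15.5 by chance), with 6 in opposite directions and a Pearson r of 0.469 across genes, which are not independent replicates.

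The comparison of oil at month 12 with oil at month 2 asked what age and a year of vehicle dosing changed. The edgeR fit called 11 genes, 6 higher and 5 lower, with 1753 at an unadjusted p below 0.05, 140 called by DESeq2 and 17 by limma-voom. Scaled by library totals alone the count was 183 (19 higher and 164 lower), and with only these 12 libraries fitted it was 190. Pira2, an immunoglobulin-like receptor of myeloid cells (chromosome 7, 3,836,812 to 3,845,051), decreased by 2.89 (SE 0.44, adjusted p = 0.00248). Me1, a source of NADPH for lipid synthesis (chromosome 9, 86,581,371 to 86,695,953), decreased by 1.34 (SE 0.22, adjusted p = 0.0036). Mup13 rose by 2.39. These 3 genes kept their call in each fit without 1 library. The other named genes, Moxd1 (3.45), Mup9 (2.67), Slc39a4 (0.95), Pdgfc (0.94), Slc17a8 (-1.23), Fnip2 (-0.83) and Sh3bgrl2 (-0.49), each lost it without month 2 oil replicate 5 (3.19, 2.59, 0.88, 0.88, -1.09, -0.82 and -0.40), and each without at least 1 of month 12 oil replicates 2, 3 and 5. The count of called genes was 20, 17, 5, 4 and 18 without month 2 oil replicates 1, 3, 4, 5 and 6, and 19, 4, 19, 5 and 28 without month 12 oil replicates 1, 3, 4, 5 and 6.

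Targets of the fatty acid sensor PPAR alpha were not called singly between the oil groups (0 of 32, and 12 lower adjusted over the list alone), and the list median was -0.30 (adjusted p = 1.67e-12, and adjusted p = 0.28 with an estimated correlation). Cyp4a14 (-3.38, adjusted p = 0.0585), Ppara (-0.88) and Pex11a (-0.50) had its smallest p-values. Acute phase genes had a median of 0.51 (0 called, 11 higher adjusted over the list alone, adjusted p = 8.77e-11, and adjusted p = 0.332 with an estimated correlation), with Orm2 (2.92), Orm3 (2.02) and Orm1 (0.85) foremost. Lipogenesis genes fell in 1 of 28, Me1 (10 lower adjusted over the list alone), with Plin4 (-1.52) and Pparg (-0.88) not called (adjusted p = 1.1e-09, and adjusted p = 0.209 with an estimated correlation). The clock genes were called as a list as well (median -0.65, with 5 higher and 12 lower adjusted over the list alone, adjusted p = 8.16e-05, and adjusted p = 0.28 with an estimated correlation). The log2 ratio of Arntl to Dbp ran from -5.20 to -2.90 in month 2 oil and from -3.92 to 2.98 in month 12 oil. With this ratio as a covariate 7 genes were called, and Slc39a4, Pdgfc, Slc17a8, Fnip2 and Sh3bgrl2 were not. Between the oil groups, 15 of the 38 lists were called with the preset correlation and 0 with the estimated one.

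Month 2 oil was compared with month 0 control to show the baseline against which CCl4 was read. Acute phase transcripts of the liver were far lower in month 2 oil than at month 0, and neutrophil and interferon transcripts were also lower, whereas fatty acid oxidation and plasma cell transcripts were higher, and of these lists the acute phase list alone was also called with an estimated correlation. A2m, a protease inhibitor (chromosome 6, 121,635,376 to 121,679,227), stood at 420 ± 591 CPM at month 0 and 0.214 CPM in month 2 oil (log2 fold change -10.9, SE 1.65, adjusted p = 7.58e-06, not called by limma-voom). Lcn2, an iron carrier of injured hepatocytes, dropped from 1675 ± 938 to 11.4 ± 12.4 CPM. Saa1, a serum amyloid (chromosome 7, 46,740,497 to 46,742,980), dropped from 20050 ± 2596 to 190 ± 269 CPM (log2 fold change -6.72, SE 1.1). Igkc rose from 4.13 ± 1.65 to 72.8 ± 70.2 CPM.

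Between these groups 4797 genes were called, 2274 higher and 2523 lower in month 2 oil, 557 and 496 of them at least 2-fold, and 6365 had an unadjusted p below 0.05. Library totals alone shifted the median by 0.227 and called 5270 higher and 1028 lower. With the ratio of the clock genes Arntl and Dbp as a covariate, 2345 were called. Rgs16 (5.59), Gpnmb (4.53), Mup-ps12 (4.11) and Ccl8 (4.08) rose, Cyp2b9 (4.33) lost its call without month 2 oil replicate 5 (1.10), and Saa2 (-7.62), Lcn2 (-7.19) and Orm2 (-6.80) fell. Acute phase genes fell in 23 of 24, including Itih4 (-2.73), Orm1 (-3.28) and Itih3 (-3.02), with a median of -2.93 (adjusted p = 1.38e-30, and adjusted p = 0.0268 with an estimated correlation). Fatty acid oxidation genes rose in 23 of 32 (25 adjusted over the list alone), including Acot1 (3.47), Fabp1 (1.71) and Cpt1a (1.11, not called with the clock covariate), with adjusted p = 4.4e-09, and adjusted p = 0.564 with an estimated correlation. B and plasma cell markers rose in 15 of 19, including Cd79b (1.84), Iglc1 (3.39) and Igkc (4.14), with adjusted p = 2.94e-06, and adjusted p = 0.564 with an estimated correlation. Neutrophil markers fell in 7 of 10, including Retnlg (-2.71), Mmp8 (-3.57) and S100a9 (-3.13), with adjusted p = 4.33e-05, and adjusted p = 0.564 with an estimated correlation. Interferon response genes fell in 18 of 28 (21 adjusted over the list alone), including Zbp1 (-2.24), Stat2 (-0.88) and Isg15 (-1.30), with adjusted p = 8.83e-06, and adjusted p = 0.613 with an estimated correlation. Clock genes rose in 10 and fell in 4 of 21 (10 and 5 adjusted over the list alone), with no call for the list (adjusted p = 0.161). Nr1d1 (2.52) and Nr1d2 (1.56) rose, and Arntl (-2.60), Cry1 (-1.14), Nfil3 (-1.59) and Tspan4 (-1.21) fell. Of the 38 lists, 17 were called with the preset correlation and 1 with the estimated one.

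Successive CCl4 groups were compared to follow the course of exposure. From month 2 to month 6, cholesterol synthesis genes rose. Of the Kupffer cell markers 3 of 16 fell, and their list was called lower with the preset correlation alone. Mvd, an enzyme of the mevalonate pathway (chromosome 8, 122,433,601 to 122,443,422), rose by 1.69 (SE 0.31, adjusted p = 0.00934), and Cd163 decreased by 2.63 (SE 0.23, adjusted p = 8.92e-09). In total 77 genes were called, 42 higher and 35 lower, with 1395 at an unadjusted p below 0.05. The count was 119 by DESeq2, 38 by limma-voom, 12 without month 2 CCl4 replicate 6, and 40, 16, 25, 48 and 44 without month 6 CCl4 replicates 1, 2, 3, 4 and 6. It was 14 with the ratio of Arntl to Dbp as a covariate. With the 4 libraries with transcripts of other tissues or blood cells left out it was 21. The log2 ratio ran from -5.33 to 2.96 at month 6 and from -5.70 to -0.999 at month 2. The lowest fold changes were those of intestinal genes carried by month 2 CCl4 replicate 6, S100g (-7.87), Sis (-7.47), Krt20 (-7.09), Fcgbp (-6.23) and Vil1 (-5.98), and none of these was called without it (-0.74, 0.47, 0.05, -0.99 and -0.54). The highest were Tubb2a (2.54), Cdh19 (2.31), Sytl5 (1.93), Cyp2c38 (1.82) and Mvd. Tubb2a lost its call without month 2 CCl4 replicate 6 (2.45) or month 6 CCl4 replicate 2 (1.83), and Cyp2c38 without month 2 CCl4 replicate 6 (1.71) or month 6 CCl4 replicate 6 (1.40). Cholesterol synthesis genes rose in 11 of 25 (22 adjusted over the list alone), including Hsd17b7 (1.09) and Cyp51 (0.97), with a median of 0.75 (adjusted p = 3.1e-35, and adjusted p = 0.0262 with an estimated correlation). Cyp51 lost its call without month 2 CCl4 replicate 6 (0.90) or month 6 CCl4 replicate 2 (0.75). Kupffer cell markers fell in 3 of 16 (6 adjusted over the list alone), Cd163, Timd4 (-1.95) and Xlr (-1.14), with adjusted p = 1.04e-10, and adjusted p = 0.267 with an estimated correlation. Timd4 lost its call without month 2 CCl4 replicate 3 or 6 or month 6 CCl4 replicate 2, 3, 5 or 6 (between -2.06 and -1.76), and Xlr without month 2 CCl4 replicate 1, 5 or 6 or month 6 CCl4 replicate 2, 3, 4 or 6 (between -1.21 and -0.99). Lipogenesis genes rose in 2 of 28, Pparg (1.30) and Me1 (1.20), and in 10 adjusted over the list alone, with 1 lower (adjusted p = 5.49e-10, and adjusted p = 0.0925 with an estimated correlation). Acacb (0.96) was not called. Of the 38 lists, 14 were called with the preset correlation and 1 with the estimated one.

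From month 6 to month 12 of CCl4 the female-biased, cell cycle and oncofetal genes rose and cholesterol synthesis genes fell, the cell cycle and cholesterol lists with no call at an estimated correlation. Igf2, a fetal growth factor, rose by 6.68 (SE 0.63). Here 6007 genes were called, 3160 higher and 2847 lower, with 1089 and 384 at least 2-fold, and 7131 had an unadjusted p below 0.05. Library totals alone shifted the median by 0.18 and called 4823 higher and 1284 lower. Cyp2a4 (9.45), Vil1 (8.27), Apela (7.92) and Obp2a (7.34, not called by limma-voom) were among the highest fold changes, and Mup7 (-7.74), Mup-ps8 (-6.95), Hsd3b5 (-6.59), Mup11 (-6.06) and Mup12 (-5.89) the lowest. Vil1 in month 12 CCl4 ran from 11.6 to 187 CPM, highest in replicate 6. Male-biased genes fell in 21 of 27, including Slco1a1 (-4.81), Mup3 (-3.99) and Nudt7 (-2.76), with adjusted p = 8.77e-12, and adjusted p = 0.133 with an estimated correlation. Susd4 (1.18) was the 1 that rose, and it lost its call without month 12 CCl4 replicate 6 (0.69). Female-biased genes rose in 22 of 29 (24 adjusted over the list alone), including Sult2a2 (6.62), with adjusted p = 4.01e-10, and adjusted p = 0.0333 with an estimated correlation. Cell cycle genes rose in 32 of 35 (33 adjusted over the list alone), including Mcm6 (1.87), Aurka (1.73) and Cenpf (2.08), with adjusted p = 7.21e-17, and adjusted p = 0.111 with an estimated correlation. Oncofetal genes rose in 17 of 23 (18 adjusted over the list alone), including Scd2 (2.68) and Prom1 (4.03), and Egfr (-1.33) fell, with adjusted p = 1.09e-11, and adjusted p = 0.0049 with an estimated correlation. Cholesterol synthesis genes fell in 20 of 25 (21 adjusted over the list alone), including Stard4 (-1.09), Tm7sf2 (-1.12) and Ebp (-0.94), with adjusted p = 7.54e-08, and adjusted p = 0.398 with an estimated correlation. Of the 38 lists, 18 were called with the preset correlation and 3 with the estimated one.

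Transcripts of tissues other than liver, or of blood cells, stood apart in single libraries. Sis, an intestinal disaccharidase, was at 326 CPM in month 2 CCl4 replicate 6 and at 15.7 CPM in month 2 oil replicate 2. Pancreas transcripts varied within every group and followed the third principal component (absolute Pearson r 0.914 over 36 libraries), and no difference in their levels was called between CCl4 and oil at month 2 or 12 (adjusted exact permutation p = 0.706 and p = 0.586). At month 6, where levels were not tested, the list was called lower in CCl4 (median -1.91, adjusted p = 0.00201, and adjusted p = 0.548 with an estimated correlation), with 0 of 19 genes called, and not without month 6 CCl4 replicate 3 (adjusted p = 0.0672). Neutrophil and erythroid transcripts were highest in month 2 CCl4 replicate 1. The acute phase (9.266) and Kupffer cell (5.653) levels of that library were also the highest of its group. Whether its neutrophil transcripts came from blood or from cells within the liver was not tested. Mesothelial transcripts were highest in month 6 CCl4 replicate 2, followed by month 12 oil replicate 2.

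**Figure D4:**
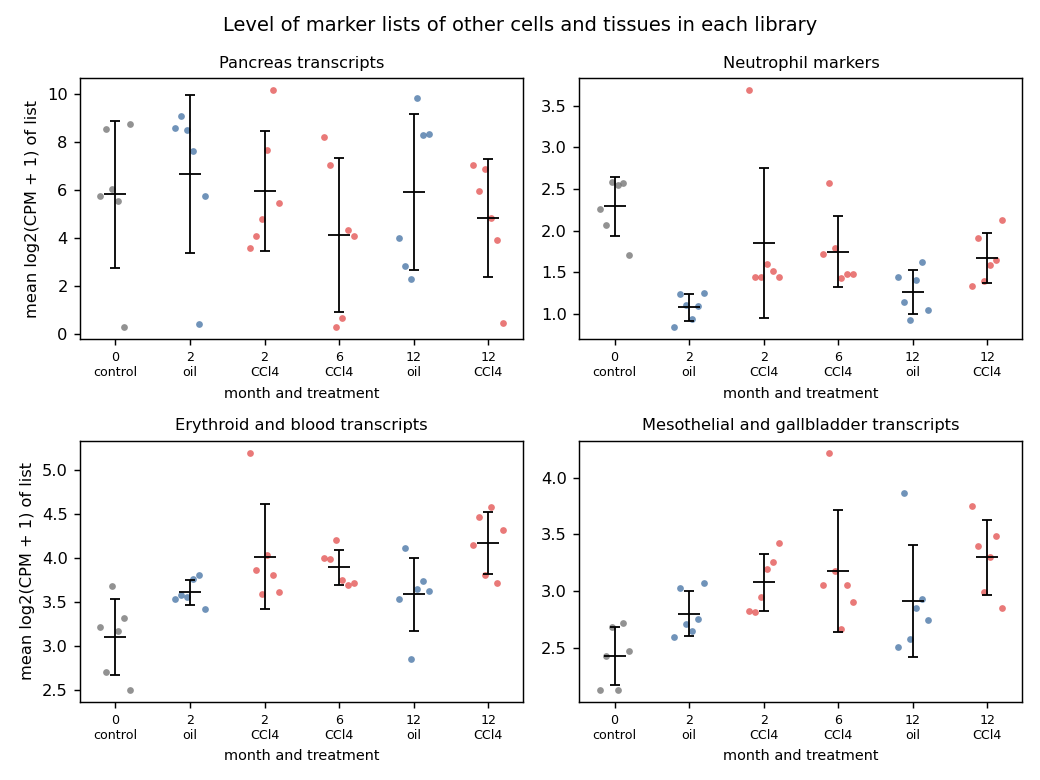
Mean level of pancreas, neutrophil, erythroid and mesothelial gene lists in each library, as log2 of CPM plus 1, by group (points are mice, bars are mean ± SD, n = 6). Pancreas levels ran from 0.388 to 9.08 among month 2 oil livers.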

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

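The tests of intestinal carry-over, of the share of hepatocytes and of reads shared within gene families were chosen only after the results were seen, and those of time of day, pancreas carry-over and regrouping were set down before their values were computed. A mouse was taken as standing apart where the gap to its nearest neighbour was a large share of the range of the 6 values, the share given with each. This was so in 38 of 325 groups of 6, and chance alone marks about 1 in 20 groups.

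Month 2 CCl4 replicate 6 stood apart for Afp (0.698), Krt19 (0.645) and Lyz1 (0.766), and intestinal transcripts are a candidate source. Sis was at 326 CPM in this library and Fabp2 at 235 CPM. Of 22 intestinal markers listed for their known expression, after the levels of Fabp2 and Olfm4 had been seen, and outside the 27 genes picked for being far higher in this library, 95.5% (21 of 22, all but Zg16) had their highest level of the group there, against 16.3% of all tested genes, and 20 were at least 4 times the highest of the other 5 mice, with Alpi at 152 CPM and Clca1 at 77.8 CPM. Of these markers 4 averaged at least 1 CPM in the other 5 mice. The levels are consistent with intestine carried over into 1 library. At month 12, Vil1 was higher in the CCl4 group (47.3 ± 68.6 CPM, n = 6), with replicate 6 apart (0.743). Of the 27 picked genes 12 were called higher there. Of the 26 other than Vil1, 7.69% (2 of 26) were less than 4-fold below the level that Vil1 would predict from the profile of the month 2 library, and Sis averaged 0.203 CPM, so carry-over is unlikely to account for the level of Vil1 there. Carry-over at a lower level stays open, and expression by liver cells was not tested.

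Sex-biased hepatocyte genes at month 12 may reflect a lower share of hepatocytes, reads shared within gene families, or a change in the hormone signals that set sex bias. A lower share would lower both lists, yet the female-biased list had a median of 2.37. Outside gene families the male-biased median was -2.47 (9 of 9 lower) and the female-biased median 1.54 (8 of 10 higher), so shared reads are unlikely to explain the direction. The hormonal explanation was not tested, and the explanations named here are not a complete set. Oncofetal and cell cycle genes also rose at month 12. Whether these changes share a source with the sex-biased ones was not tested.

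Acute phase genes were lower in month 2 oil than at month 0 by a list median of -2.93, and time of day, pancreas carried over into the libraries or an inflammatory state of the month 0 mice could each produce a difference. With the pancreas level as a covariate the median was -2.88 (23 of 24 lower), so this covariate does not account for it. With the clock ratio it was -2.69 (22 of 24 lower). That ratio ran from -1.71 to 3.85 at month 0 and from -5.20 to -2.90 in month 2 oil. As these ranges do not overlap, the clock covariate cannot decide whether time of day accounts for the difference. The month 0 mice differ from month 2 oil in age, dosing and possibly sampling date together, which these data cannot separate, and inflammation was not tested.

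The other mice that stood apart are given as values. In month 2 oil, replicate 6 was high for myofibroblast markers (0.755), adipose and muscle transcripts (0.84) and Gldn (0.711) and low for Gstm3 (0.696), replicate 1 was apart for Cyp2c40 (0.664) and Cyp2c69 (0.781), replicate 2 was low for Fbn2 (0.838) and replicate 3 low for Mup12 (0.654). In month 2 CCl4, replicate 1 was high for neutrophil markers (0.931), erythroid transcripts (0.723), S100a8 (0.814) and Sirpb1a (0.717), replicate 2 was apart for adipose and muscle transcripts (0.759), Cyp2f2 (0.648) and Mup15 (0.664), and replicate 5 for Cyp2c69 (0.703). Month 6 CCl4 replicate 2 was apart for neutrophil (0.682), mesothelial (0.671) and immediate early genes (0.642), and for Col1a1 (0.686), Krt19 (0.647), Ly6d (0.722), Spp1 (0.808) and Timp1 (0.711), and replicate 3 for Sult2a2 (0.652). In month 12 oil, replicate 2 was apart for myofibroblast (0.653), vascular endothelial (0.813) and mesothelial markers (0.688) and for Cd3e (0.708). Replicate 6 of that group was low for Mup12 (0.662) and apart for Apela (1). Apela had 1 count in that group, which fixes its share at 1. In month 12 CCl4, Cyp2e1 was low in replicate 6 (0.776), Glul apart in replicate 2 (0.737) and Sult2a1 in replicate 1 (0.718).

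The effect of CCl4 differed between months 12 and 2 for 3263 genes. Differences in log2 fold change, month 12 minus month 2, were 4.89 for Afp, 7.76 for Akr1c18, 10.1 for Apela, 8.54 for Csn3, 12.1 for Cyp2a4, 4.53 for Cyp2c40, 5.92 for Cyp2c69, 4.88 for Fitm1, 2.85 for Gstm3, 1.41 for Mki67, 4.78 for Mup-ps16, 2.33 for Spp1 and 2.04 for Tcf24. They were -2.34 for Cyp2e1, -1.43 for Cyp2f2, -7.96 for Hsd3b5, -4.60 for Lyz1, -6.58 for Moxd1, -6.88 for Mup11, -7.87 for Mup12, -4.90 for Mup15, -4.04 for Mup17, -10.0 for Mup7, -5.95 for Mup9 and -6.71 for Saa1. The value for Lyz1 includes month 2 CCl4 replicate 6, without which its month 2 effect was 1.67 and not called. Called lists had positive median differences for cholangiocyte (1.1), monocyte-derived macrophage (0.416), T and NK cell (0.862), dendritic cell (0.344) and vascular endothelial markers (0.413), and for glutathione (0.857), lipogenesis (0.568), cell cycle (1.54), p53 and senescence (0.535), interferon (0.42), oncofetal (2.43) and female-biased genes (2.15). Negative medians were those of quiescent stellate (-0.577) and sinusoidal endothelial markers (-0.607), and of pericentral (-0.519), periportal (-0.273), xenobiotic (-0.398), bile acid (-0.609), acute phase (-0.784), male-biased (-1.72) and urea cycle genes (-0.692). Of these 21 lists the oncofetal, female-biased and glutathione lists were also called with an estimated correlation, and the other 18 were not. Without 1 library the dendritic cell list lost its call in 8 of 24 fits, the macrophage list in 6 and the p53 and senescence list in 2. Mean levels of the acute phase list were 8.094 and 8.059 in CCl4 at months 2 and 12, and 7.862 and 8.65 in oil. The difference for that list thus lay mainly in the oil groups. For lipogenesis the levels were 6.137 and 6.446 in CCl4 and 6.367 and 5.932 in oil, so both treatments moved.

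Regrouping the same mice at random tested how many genes chance groupings call in fits of the compared groups alone. The real grouping called 2182 genes at month 2, 1875 at month 6, 6226 at month 12, 3196 for the interaction, 4498 between month 2 oil and month 0, and 4655 between CCl4 months 12 and 6. The highest of the other groupings called 925, 1426, 2077, 96, 497 and 1, so that 1 grouping, the real one, reached the real count in each, among 70 drawn for the interaction and 100 for the others. The interaction had 100 at first, with the same outcome, and its draws were cut for run time after that outcome was known. For oil at month 12 against month 2 the real count of 190 stood barely above the highest other, 187. For CCl4 at month 6 against month 2, 2 of 100 groupings reached the real count of 34, and another grouping called 410. A split that calls several times the real number points to structure of the samples other than the months, whose source was not tested. In each comparison the share of groupings that reached the real count was below 0.05, without correction over the comparisons. These fits differ from the main fit, which called 11 genes between the oil groups and 77 between CCl4 months 6 and 2. The regroupings therefore do not exclude chance for the genes called in the main fit. For CCl4 at month 6 against month 2 the count also says little about time.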

How the results depend on the processing

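The alternatives with the pancreas and clock covariates, with 4 libraries left out, and of lists and list levels without each library were chosen only after the results were seen. Named genes stayed on their side of the threshold and kept their direction in 8010 fits, were weaker in 313, stronger in 109 and reversed in 27, and for lists these numbers were 6543, 320, 192 and 13, and for list levels without each library 403, 20, 9 and 0. RLE size factors moved no count of called genes by more than 1.5 times. Where not stated, the cause was not tested.

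Scaling by library totals alone, which leaves composition in the fold changes, called 3339 genes at month 2, 9061 at month 6, 5553 for the interaction and 183 between the oil groups, and raised the share of month 2 effects kept at month 12 from 70.4% to 87.9%. That share was 67.7% with no low-count filter. A filter of 1 CPM in 6 samples called 26 between the oil groups. DESeq2 called 140 between the oil groups and 119 between CCl4 months 6 and 2, limma-voom 17 and 38, and fits of the compared groups only 190 and 34. Against month 0, 6562 genes were called at month 2 and 5827 at month 6, and against month 12 oil alone 1115 at month 6. With the pancreas covariate 19 were called between the oil groups. With the clock covariate 7 were called there, 2345 between month 2 oil and month 0, and 14 between CCl4 months 6 and 2. With the 4 libraries left out, 884 were called at month 2, 6 between the oil groups and 21 between CCl4 months 6 and 2. This was in part because fewer mice were tested. At month 6 that fit called 1388 genes higher and 811 lower. It left out month 12 oil replicate 2 (mesothelial level 3.865) and kept month 6 CCl4 replicate 2 (4.216). Without the first alone the month 6 count was 2376, and without the second alone it was 1049. With an estimated correlation 0 lists were called at months 2 and 6 and between the oil groups, 3 at month 12, for the interaction and between CCl4 months 12 and 6, and 1 in each of the other comparisons.

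Leaving out each library in turn gave 1049 to 2376 genes at month 6, 4 to 28 between the oil groups and 12 to 111 between CCl4 months 6 and 2, with ranges of 1102 to 1753 at month 2, 7132 to 7831 at month 12, 2936 to 3396 for the interaction, 4032 to 4788 between month 2 oil and month 0 and 5463 to 6271 between CCl4 months 12 and 6. With the replicate number as a block, 19 genes were called between the oil groups and 50 between CCl4 months 6 and 2, and no other count moved by more than 1.5 times. No pairing of mice by number was seen: in 0 of 15 pairs of groups was each correlation of same-numbered mice above 0.1 (range -0.659 to 0.633). This strict criterion cannot show that the numbers mark nothing shared. In month 2 CCl4 the log2 ratio of Arntl to Dbp fell with each number, from -0.999 in replicate 1 to -5.70 in replicate 6. No other group fell at each step. Month 6 CCl4 had a similar order, with 2.17 and 2.96 in replicates 1 and 2 and -5.09 in replicate 6. Whether the numbers follow the order of sampling was not tested.

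Reversed log2 fold changes under totals alone were Stab2 0.396, Gstt1 0.121, Sod1 0.0437 and Sod2 0.0899 at month 12, and under limma-voom Cftr at month 2 (-0.0931). Against month 0 they were Cdkn1a -2.19, Saa1 -5.18, S100a8 -0.709, Retnlg -0.716 and S100a9 -0.706 at month 2, Spp1 -0.521, Cdkn1a -1.84, Ly6d -0.0777, Lss -0.401, Mvd -0.526 and Saa3 -2.42 at month 6, and Timp1 2.00, Efemp1 0.48, Cat 0.0812 and Gstt1 0.0134 at month 12. With the clock covariate Arntl between month 2 oil and month 0 was 0.096, by construction, since Arntl enters the covariate.

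Genes called only without 1 library, other than those given at month 12, were at month 2 Mki67 (1.08 without month 2 oil replicate 2) and Krt19 (1.59 to 1.66 without month 2 CCl4 replicate 1, 2 or 3), at month 6 Alb (-0.42 without month 12 oil replicate 2), between the oil groups Cyp4a14 (-4.3 to -3.6, in 3 fits), Plin4 (-1.63 to -1.57, in 4), Pparg (-1.03 and -0.995), Orm2 (3.13 and 3.35), Orm3 (2.21) and Ppara (-0.996), and between CCl4 months 6 and 2 Acacb (1.08).

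Without month 2 CCl4 replicate 6, Cftr at month 2 was -1.12 (leaving out each library gave -1.12 to 3.90), and between CCl4 months 6 and 2 Sis was 0.473 (-7.75 to 0.473) and Krt20 0.0522 (-7.36 to 0.0522), since that library holds nearly all of their month 2 counts. With the 4 libraries left out these were -0.449, 0.393 and 0.239. Lists that turned direction are given by their camera adjusted p under the alternative. Under totals alone at month 6 these were the myofibroblast (adjusted p = 0.996), B and plasma cell (adjusted p = 0.831), oncofetal (adjusted p = 0.0431), female-biased (adjusted p = 0.446), clock (adjusted p = 0.00528) and erythroid lists (adjusted p = 0.802). Between the oil groups the clock covariate turned the macrophage (adjusted p = 0.0222), pericentral (adjusted p = 0.036) and clock lists (adjusted p = 0.794), and the pancreas covariate turned the pancreas list (adjusted p = 0.00345), as it did at month 2 (adjusted p = 0.0296), by construction. Between CCl4 months 6 and 2 the neutrophil list turned with the 4 libraries left out (adjusted p = 0.0269) and without month 2 CCl4 replicate 1 (adjusted p = 0.0326, with 0.0326 to 0.929 over the fits without each library). Depth limits folds of genes near 0 counts in oil, such as Sult2a2, Sult2a1 and Apela, to the bounds and intervals given with them. Groups of 6 mice limit the smallest exact permutation p of a list level to 0.00216, and the month 6 comparison has no oil mice of the same age.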

Other observations

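The relation between mesothelial and matrix transcripts among oil mice was tested only after it was seen. Several cell types and responses not described above moved at month 12 of CCl4. T and NK cell markers rose in 15 genes, among them Gzmk (4.13, SE 0.74), Ccl5 (1.61) and Cd8a (1.33), with a list median of 0.905 (adjusted p = 0.00189, and adjusted p = 0.418 with an estimated correlation). Dendritic cell and antigen presentation genes rose in 12, including Cd74 (2.00), H2-Eb1 (2.14) and H2-Ab1 (1.93), with adjusted p = 0.000334, and adjusted p = 0.173 with an estimated correlation. Vascular endothelial markers rose in 16 and fell in 1, Rspo1 (-1.25), with Esm1 (6.01), Pdgfb (2.22) and Cd36 (2.06) among the higher ones (adjusted p = 3.96e-06, and adjusted p = 0.0724 with an estimated correlation). Cd36 is also a member of the lipogenesis and female-biased lists. Genes of the list of p53 targets and senescence rose in 15 and fell in 1, Perp (-0.25), with Phlda3 (3.27) and Cdkn2b (3.78) as examples (adjusted p = 0.000417, and adjusted p = 0.272 with an estimated correlation). Interferon response genes rose in 16, including Mx1 (1.44) and Psmb8 (0.79), and fell in 2, Mx2 (-0.70) and Stat2 (-0.30), with adjusted p = 0.000417, and adjusted p = 0.497 with an estimated correlation. Small decreases here are relative to the median gene, which library totals alone moved by 0.556. Sinusoidal endothelial markers fell in 10 and rose in 3, with no call for the list (adjusted p = 0.0868) except without month 12 CCl4 replicate 1, 3 or 4 (adjusted p = 0.022, adjusted p = 0.0418 and adjusted p = 0.0256).

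Among resident macrophage markers Cd163 fell in CCl4 at months 6 and 12 (-2.92 and -2.89), while the Kupffer cell list was not called at month 12 (adjusted p = 0.939), with 5 members higher and 2 lower, C1qa (0.95) and C1qb (0.91) among the higher. Mitochondrially encoded transcripts had a list median of -0.35 at month 2 (adjusted p = 7.34e-05, and adjusted p = 0.407 with an estimated correlation) and of -0.45 at month 6 (adjusted p = 9.33e-08, and adjusted p = 0.27 with an estimated correlation). In levels per mouse at month 2, sinusoidal (0.295) and vascular endothelial markers (0.332) were higher and mitochondrial transcripts lower (-0.353), each at the smallest p that exact permutations can give, 0.00216. At month 12, T and NK cell markers (0.382, adjusted exact permutation p = 0.0142), myofibroblast markers (0.597, adjusted exact permutation p = 0.039) and erythroid transcripts (0.586, adjusted exact permutation p = 0.048) were higher. The last 2 each lost their call in 10 of 12 fits without 1 library, which compared fewer mice. Their differences ran from 0.523 to 0.75 and from 0.439 to 0.692 over the 12 fits. In all 13 of 36 list levels were called. The median of mesothelial genes at month 12 was -0.39 and their mean 0.872, and the list was not called (adjusted p = 0.369).

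The mean TMM factor was 0.797 at month 0, 0.937 in month 2 oil, 0.873 in month 12 oil and 1.27 in month 12 CCl4. Month 12 oil (0.781 to 1.014) overlapped month 0 (0.757 to 0.868), and the difference was not tested. Alb took 4.40% of counts at month 0, 6.02% in month 2 oil, 5.42% in month 2 CCl4, 4.89% in month 6 CCl4, 4.19% in month 12 oil and 7.24% in month 12 CCl4. The first principal component held 32.2% of the variance, the second 16.3% and the third 12.1%.

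Matrix transcripts varied among oil mice, and a candidate explanation is that some pieces of liver held more capsule, with its mesothelium. Over 12 oil mice, after subtracting each group's mean, the matrix and mesothelial list levels correlated with Pearson r = 0.828 (permutation p = 0.00207, adjusted 0.0103 over 5 relations) and Spearman rho = 0.797 (permutation p = 0.00743, adjusted 0.0186). Without the 2 mice farthest from the median r was 0.587, and within month 2 and month 12 oil it was 0.865 and 0.834. Monocyte-derived macrophage markers correlated with the matrix list as well (r = 0.742, permutation p = 0.0112, adjusted 0.0279, and rho = 0.79, permutation p = 0.00271), with r = 0.722 without the 2 farthest mice and 0.893 and 0.677 within the months. Of the mesothelial list Upk3b was at 43.3 CPM and Gpm6a at 38.4 CPM in month 12 oil replicate 2, against at most 10.7 and 11.5 CPM in the other oil mice. Krt8 and Krt18, which hepatocytes express, were at 170 and 173 CPM in that library and not raised. The pattern would also arise if some oil mice had mild fibrosis of the capsule or the lobule, which these relations do not separate from sampling. The other relations computed, with B and plasma cell, adipose and pancreas lists, had r = 0.444, 0.353 and -0.0784.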
